A study of Homo sapiens with 6 samples.

How the data were processed

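Total RNA of Ju77 malignant mesothelioma cells was extracted with a column kit the day after plating, checked by spectrophotometer and Bioanalyser, and turned into biotin-labelled cRNA for Illumina expression arrays, per the labels' protocols. The 6 samples were 3 of cells resistant to ADI-PEG20 and 3 of parental cells, grouped by their titles. The deposited table of the whole series gives an intensity and a detection p-value for each of 47225 probes on each array, with no background correction or normalisation named. Per the file headers the intensity columns hold the average signal of a probe. The detection p-values deposited with them move in steps of 1 in 770, and what they were computed against is not given in the sources used here. The deposited log2 values of the same arrays, in a separate table, have array medians from 6.98 to 6.99. For parental replicate 1 they equal the log2 of the intensity (largest difference 1.55e-06), and for every array they keep the rank order of the intensities (rank correlation 1). Their scale is therefore log2, without centring of genes. The method behind them is not given in the sources used here.

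In 3269 consecutive rows the intensity and the detection column were exchanged on all arrays, and the value in the detection column was on another scale. Taken as the natural log of the intensity, these values fell in place, with a rank correlation of 1 between restored intensities and the deposited log2 values on each array, against at most 0.906 for base 2 and 0.873 for base 10. The rows were restored in that way. Of them 602 carry a gene name, and 125 of the tested genes use one of them.

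Intensities were background corrected with the normexp model fitted from the detection p-values and an offset of 16, quantile normalised and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). A probe was kept where its detection p-value was under 0.05 on all 3 arrays of at least 1 group, which left 17843 probes. Gene names came from the platform annotation, updated by gene identifier to the GRCh38.p14 gene table, which held the gene of 99.9% of the named probes. Of all probes 30111 had 1 gene name, 8 had several and 17106 were unlisted, and none was named from a probe with several. A gene with several kept probes was represented by the one with the highest mean, which gave 10672 genes. Of 2830 genes with several kept probes 28 had probes called in opposite directions. No genome build is given for the arrays, so no coordinates are printed, and the gene table was used only for names, chromosomes and the order of neighbouring genes.

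The groups were compared with lmFit and eBayes in limma, without a covariate, and p-values were adjusted by Benjamini-Hochberg over all 10672 genes, two-sided, at a threshold of 0.05. A gene with no probe detected on any array of its dimmer group has only a bound. It is given as at least N-fold, from the brighter group's mean against, per array of the dimmer group, the higher of the lowest detected signal and the gene's own signal, and 202 called genes had one. Gene lists, 32 in all, were tested with camera with a preset correlation of 0.01, with an estimated correlation and with fry, where they had at least 3 measured genes (29 lists). Adjusted p-values of lists cover these 29. The lists are arginine synthesis and breakdown, polyamine metabolism, amino acid transporters, the ATF4 amino acid stress response, cytosolic tRNA synthetases, transcription factors acting on the ASS1 promoter, MYC targets in ribosome biogenesis, glycolysis, hypoxia targets, the TCA cycle, nucleotide synthesis, cholesterol and fatty acid synthesis, NRF2 targets, autophagy and lysosome, the unfolded protein response, interferon-stimulated genes, antigen presentation, inflammatory cytokines, mesenchymal and matrix genes, epithelial genes, receptor tyrosine kinases, S phase, G2 and M phase, p53 targets, chromatin modifiers, drug efflux pumps, reference genes, and markers of mesothelial cells, fibroblasts, leukocytes, endothelium and lung epithelium. A few genes stand in more than 1 list, such as B2M among antigen presentation and reference genes.

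The groups, the tests, the lists and the rule for named genes were fixed before the data were examined. The rule names 13 genes whatever their result (ASS1, ASL, OTC, ARG2, SLC7A1, ODC1, AMD1, SRM, SMS, SAT1, SMOX, MYC and HIF1A), the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose brighter group is detected on all arrays, and up to 4 called members with the largest change in each described list.

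The functions for correction, filter, fit and list test were tested on simulated arrays with 200 genes changed, built from the parental mean intensities and the spread within both groups, in which 12110 genes were tested. Of changed and tested genes, 33 of 66 were recovered at a simulated fold of 1.5, 51 of 66 at 2 and 60 of 65 at 4, with median fitted folds of 1.46, 1.91 and 3.59. Of 11913 unchanged genes 16 were called. A list of 25 genes raised by 0.8 on the log2 scale passed the list test with the preset and with the estimated correlation. None of 29 unchanged lists passed with the preset correlation. Noise was drawn for each probe apart and lists were drawn at random. The simulation therefore does not show how often a list whose genes move together would pass. No pair of arrays held identical values. Arrays correlated across genes at 0.993 to 0.996 within a group and at 0.962 to 0.965 between groups, and genes are not independent replicates. Left out were unnamed probes, which were tested apart from the genes, and the 3 lists with too few measured genes.

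Alternatives were no background correction, normexp without detection p-values, an offset of 50, cyclic loess, scaling to a common median, no filter, a stricter filter, the mean of a gene's probes, the deposited log2 values, an intensity trend, array weights, the replicate number as a block, leaving out each array in turn, an estimated correlation for lists, and windows of 1 and 5 Mb around ASS1. Added after the data were seen were fits without the exchanged rows, the other ASS1 probe, and fits without the genes of chromosome 22, or of chromosome 22 and the first of 4 equal parts, by gene order, of chromosomes 7 and 8. Figures were drawn with matplotlib 3.10.9.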

Results

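Gene expression was measured in Ju77, a human malignant mesothelioma cell line, in cells resistant to ADI-PEG20 and in parental cells. ADI-PEG20 is a pegylated arginine deiminase, an enzyme that breaks down arginine outside the cell, and is directed at tumour cells that make little argininosuccinate synthetase (ASS1) and so cannot rebuild arginine from citrulline. RNA was taken the day after plating and hybridised, as biotin-labelled cRNA, to Illumina expression arrays with 47225 probes. There were 3 resistant and 3 parental arrays. Between 19024 and 20113 probes per array were detected, and the mean probe intensity was 431 ± 20.1 (SD, n = 3) on the resistant arrays against 480 ± 16.1 (SD, n = 3) on the parental arrays. The single comparison of the series asks which genes differ between the resistant and the parental cells. All values below are resistant minus parental on the log2 scale after background correction and quantile normalisation, over 10672 detected genes and 3 arrays per group, and the number of arrays limits their precision. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. By the titles each group is a single line with repeats. Resistance therefore cannot be told apart from any other difference between the resistant and the parental line.

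ASS1, the enzyme that joins citrulline and aspartate on the way to arginine, was higher in the resistant cells. Its brightest probe (ILMN_2395451) rose from 7.12 ± 0.15 to 8.62 ± 0.26 (SD, n = 3), a log2 difference of 1.50 (SE 0.14) or 2.82-fold, with a limma adjusted p of 1.24e-04 and no overlap between the groups. Without background correction the log2 difference was 1.04, and with the deposited log2 values 1.08. A second ASS1 probe (ILMN_1708778), examined after the data were seen, gave a log2 difference of 2.65 (6.27-fold, adjusted p = 3.73e-06 over 14197 probes). ASS1 lies on chromosome 9 in the GRCh38.p14 gene table. The 41 other measured genes within 2 Mb on each side of it had a median log2 difference of 0.13, at the 77.3 percentile of runs of neighbouring genes of the same length, with 14 called higher and 4 lower. Within 1 Mb the median over 16 genes was 0.24, at the 88.2 percentile, with 7 higher and 1 lower. These medians were smaller than the ASS1 difference.

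Among the 15 measured genes of arginine synthesis and breakdown, 7 were higher and 4 lower in the resistant cells, and 7 and 5 when adjusted over the list alone. Under median scaling, which shifted the median of all genes by -0.15, 5 were higher and 5 lower. The list as a whole did not pass the camera test (adjusted p = 0.640, and adjusted p = 0.838 with an estimated correlation). DDAH2, which breaks down methylated arginines, rose by a log2 difference of 0.89, AZIN2, an antizyme inhibitor detected on 1 of the 3 parental arrays, rose by 0.82, and AGMAT, which converts agmatine to putrescine, fell by 0.91. Argininosuccinate lyase (ASL), the step after ASS1, gave a log2 difference of 0.05 with a 95% interval from -0.41 to 0.50 and was not past the threshold (adjusted p = 0.864). ARG2, the mitochondrial arginase, was detected on the parental arrays and on none of the resistant arrays, at least 1.10-fold lower (adjusted p = 0.0452), a call that was lost in 10 of 18 other settings, among them no background correction (adjusted p = 0.111). OTC, the urea-cycle carbamoyltransferase, was detected on no array. SLC7A1, the main cationic amino acid carrier for arginine, fell by 0.65 on the log2 scale (SE 0.08, adjusted p = 5.49e-04).

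Genes of the polyamine pathway, which starts from ornithine, were lower at several steps. ODC1, the ornithine decarboxylase at its entry, fell by 0.91 on the log2 scale (SE 0.07, 1.87-fold, adjusted p = 5.78e-05). AMD1, which supplies the aminopropyl donor, fell by 0.55, spermine synthase (SMS) fell by 0.42, and spermine oxidase (SMOX) fell by 0.81, or by 0.44 without background correction, each past the threshold. EIF5A2, a relative of the spermidine-modified factor EIF5A, fell by 1.50, and ATP13A3, a polyamine transporter, fell by 0.83. The largest change in the list was a rise, that of the transporter SLC12A8, by 1.59 (SE 0.17, 3.01-fold, adjusted p = 2.13e-04). The acetyltransferase SAT1, which feeds polyamine breakdown and export, rose by 0.37 (adjusted p = 0.0071), a call that was lost when arrays were scaled to a common median (adjusted p = 0.129). Spermidine synthase (SRM) was lower by a log2 difference of -0.21 but not past the threshold (adjusted p = 0.0582), which it passed in 8 of 19 other settings. Of 25 measured polyamine genes 10 were lower and 4 higher, and 11 and 4 when adjusted over the list alone. Under median scaling 14 were lower and 1 higher, and the median moved from -0.21 to -0.40. Relative to all genes, whose median shifted by -0.15, it was -0.25 against -0.21. The list did not pass the test (camera adjusted p = 0.0572, and adjusted p = 0.194 with an estimated correlation), and 9 of 21 other settings took it past the threshold. Among these settings, array weights and the intensity trend were not passed to the list test and so repeat the main one.

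Of the transcription factors known to act on the ASS1 promoter, HIF1A rose by 0.70 on the log2 scale (SE 0.15, adjusted p = 0.00616), and BHLHE40, also called DEC1, rose by 1.11. SP4 fell by 0.79 and lies in a stretch of chromosome 7 whose genes were mostly lower. SP1 fell by 0.27 (adjusted p = 0.0451), a call that was lost in 9 of 19 other settings, among them cyclic loess (adjusted p = 0.0611). MYC gave a log2 difference of 0.09 with a 95% interval from -0.18 to 0.37 (adjusted p = 0.554). With 2 of the 5 measured members higher and 2 lower, also when adjusted over the list alone, the list was not past the threshold (camera adjusted p = 0.826, and adjusted p = 0.854 with an estimated correlation).

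**Figure D1:**
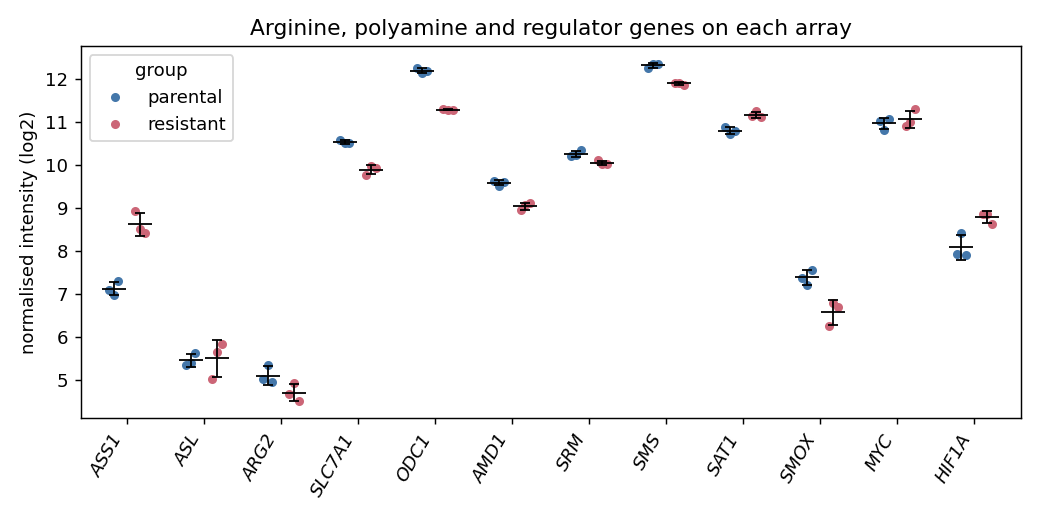
Normalised log2 intensity (vertical axis) of the arginine, polyamine and regulator genes named in advance, with 3 parental (blue) and 3 resistant (red) arrays per gene as points and the mean ± SD as bars. ASS1 sits at 8.62 in the resistant and 7.12 in the parental cells, ODC1 lies lower in the resistant cells, and the groups overlap for ASL and MYC.

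Transcripts of the amino acid stress response, the genes that the transcription factor ATF4 switches on when amino acids run short, were lower in the resistant cells. Of 25 measured members 20 fell and 1 rose, with a median log2 difference of -0.79, and 20 fell and 2 rose when adjusted over the list alone. TRIB3, a pseudokinase induced in this response, fell by 2.85 (SE 0.11, 7.21-fold), DDIT4, an inhibitor of mTORC1, fell by 1.40, and asparagine synthetase (ASNS) fell by 1.28. GDF15, a stress-induced secreted factor, was detected on no resistant array and was at least 2.12-fold lower. NUPR1, chosen after its value was seen, was the member that rose (log2 difference 0.46). The list passed the camera test with adjusted p = 3.23e-08, and had adjusted p = 0.0884 with an estimated correlation.

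Genes that load and import amino acids were lower as well. Of the 18 measured cytosolic tRNA synthetases, which charge tRNAs with their amino acids, 12 fell and none rose, also when adjusted over the list alone (median log2 difference -0.40, camera adjusted p = 2.53e-04, and adjusted p = 0.0884 with an estimated correlation). MARS1, TARS1 and YARS1, the methionyl, threonyl and tyrosyl enzymes, fell by 0.73, 0.65 and 0.63 on the log2 scale. GARS1, the glycyl enzyme, fell by 1.36, and it lies in the same stretch of chromosome 7 as SP4. Of 25 measured amino acid transporters 14 fell and 3 rose, also when adjusted over the list alone (median -0.47, or -0.33 with the undetected member at its bound, -0.21 without background correction and -0.0588 without the detection filter, camera adjusted p = 0.00636, and adjusted p = 0.0948 with an estimated correlation). The cationic carrier SLC7A2 fell by 2.49 and lies in a stretch of chromosome 8 whose genes were mostly lower, the neutral amino acid carrier SLC6A15 fell by 1.65, the aromatic amino acid carrier SLC16A10 fell by 1.31, and the glycine carrier SLC6A9 fell by 1.21. SLC7A2, SLC6A15 and SLC16A10 were each detected on 2 of the 3 resistant arrays. The members that rose, named after their values were seen, were SLC7A6, SLC38A7 and SLC1A3, with log2 differences of 0.55, 0.71 and 0.47.

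Interferon-stimulated genes, which encode antiviral and inflammatory proteins, rose almost throughout. Of 37 measured members 36 were higher and none lower in the resistant cells, also when adjusted over the list alone, with a median log2 difference of 1.78, or 1.59 with undetected members at their bounds, and 1.07 without background correction. OAS2, a sensor of double-stranded RNA, rose by 4.72 (SE 0.16) and was detected on 2 of the 3 parental arrays. IFIH1, the RNA sensor MDA5, rose by 3.16 (SE 0.09, 8.96-fold), GBP1, a guanylate-binding protein, rose by 2.99, and the chemokine CXCL10, detected on no parental array, was at least 5.39-fold higher. The list had camera adjusted p = 7.62e-22, and adjusted p = 0.0884 with an estimated correlation. Of 15 leukocyte markers on the array 1 was detected on all resistant arrays, and 1 on all parental arrays. That marker, CD68, was 0.25 higher on the log2 scale in the resistant cells (adjusted p = 0.0452), a call that was lost in 9 of 19 other settings, among them median scaling (adjusted p = 0.744).

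Antigen presentation genes moved in the same direction. Of 15 measured members 10 rose and none fell, also when adjusted over the list alone, and 8 and 1 under median scaling (median 0.53, camera adjusted p = 2.53e-04, and adjusted p = 0.0884 with an estimated correlation). Median scaling took the median to 0.32, or 0.47 relative to all genes. The peptide transporter subunits TAP1 and TAP2 rose by 1.46 and 0.82, the class I gene HLA-B rose by 0.85, and HLA-DMA, which loads class II molecules, rose by 1.02. Inflammatory cytokines and NF-kB targets went both ways, with 7 of 18 higher and 5 lower, also when adjusted over the list alone, and 6 and 6 under median scaling (camera adjusted p = 0.666, and adjusted p = 0.854 with an estimated correlation). The chemokines CCL2 and CCL5 rose by 2.52 and 2.00, whereas the chemokine CXCL8 fell by 2.23 and the prostaglandin synthase PTGS2 fell by 1.35.

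Mesenchymal and extracellular matrix genes were also higher. Of 30 measured members 22 rose and 1 fell, and 23 and 2 when adjusted over the list alone, with a median log2 difference of 0.78 (camera adjusted p = 3.38e-08, and adjusted p = 0.0744 with an estimated correlation). COL1A1, the alpha-1 chain of type I collagen, rose by 3.41 (SE 0.15, 10.6-fold), COL5A1 rose by 2.25, the actin-binding protein TAGLN rose by 1.94, and POSTN, a matrix protein detected on 1 of the 3 parental arrays, rose by 2.44. TWIST1, named after its value was seen, was the member that fell (log2 difference -0.36). Fibroblast markers were measured beside them: of 12 on the array 2 were detected on all resistant arrays and 3 on all parental arrays. Of the 3 measured markers MFAP5, a microfibril protein, rose by 3.06 and FBLN1 was at least 1.13-fold lower, also when adjusted over the list alone (camera adjusted p = 0.583, and adjusted p = 0.723 with an estimated correlation). FBLN1 lies on chromosome 22, whose genes were mostly higher.

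Genes of G2 and M phase and MYC targets in ribosome biogenesis were lower, targets of p53 were higher, and S phase genes did not shift as a list. Of 31 measured G2 and M phase genes 19 fell and 1 rose, and 20 and 1 when adjusted over the list alone (median -0.40, camera adjusted p = 6.10e-05, and adjusted p = 0.0884 with an estimated correlation), with MKI67 lower by 0.84 and the mitotic activator CDC20 by 0.82. MKI67 had no probe detected at 0.01 on all arrays. The 25 measured S phase genes did not pass the test, with 2 higher and 5 lower, also when adjusted over the list alone, 2 and 10 under median scaling, and 6 and 7 without background correction, RFC4 lower by a log2 difference of -0.58 and CCNE1 higher by 0.46 (camera adjusted p = 0.893, and adjusted p = 0.962 with an estimated correlation). Of 33 measured MYC targets in ribosome biogenesis 19 fell and none rose, also when adjusted over the list alone (median -0.34, camera adjusted p = 7.46e-05, and adjusted p = 0.225 with an estimated correlation). TBRG4 fell by 1.09, and the ribosomal RNA processing factors RRP9 and NOP16 fell by 1.00 and 0.92. Of 18 measured p53 targets 9 rose and 1 fell, also when adjusted over the list alone (median 0.27, camera adjusted p = 0.00433, and adjusted p = 0.0948 with an estimated correlation). Under median scaling 7 rose and 2 fell, with a median of 0.11, or 0.26 relative to all genes. TP53INP1, TP53I3 and SESN1 rose by 1.50, 1.22 and 1.12, and the cell cycle inhibitor CDKN1A rose by 0.79.

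**Figure D2:**
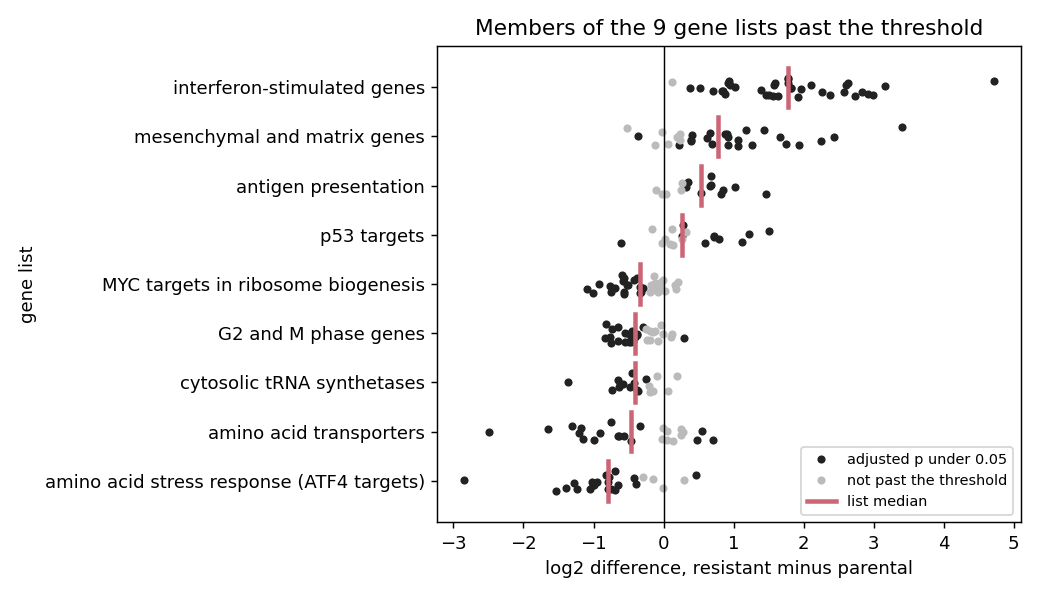
Log2 difference between resistant and parental cells (horizontal axis) for each measured member of the 9 gene lists past the camera threshold with the preset correlation, with genes at an adjusted p under 0.05 in black, other genes in grey and the list median as a red bar. Interferon-stimulated genes have the highest median (1.78) and amino acid stress response genes the lowest (-0.79).

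The largest single rise was that of SPOCK1, a matrix proteoglycan, at 5.57 on the log2 scale (SE 0.13), with detection on 2 of the 3 parental arrays. KYNU, the kynureninase of tryptophan breakdown, rose by 4.59 (SE 0.07, 24.1-fold), the ubiquitin-like modifier UBD rose by 3.88, NREP rose by 3.55, the actin-bundling protein LCP1 rose by 3.34, C5orf46 rose by 3.25, and the ubiquitin ligase subunit FBXO32 rose by 3.11. UBD was detected on 2 and C5orf46 on 1 of the 3 parental arrays. Among the falls, the globin pseudogene HBBP1 was at least 34.2-fold lower, SUN3 at least 14.5-fold lower, the hyaluronan synthase HAS2 at least 8.60-fold lower and BEX2 at least 6.59-fold lower, each with no detection on a resistant array. The beta-tubulin TUBB2B fell by 4.35 (SE 0.12), KISS1, which encodes the kisspeptins, fell by 4.31, the tight junction protein CLDN11, detected on 2 of the 3 resistant arrays, fell by 3.77, FAM167A fell by 3.21 and the proteoglycan biglycan (BGN) fell by 3.20. The carboxypeptidase-like CPVL was lower (adjusted p = 3.36e-07), but the probe used was detected on no resistant array, so no fold is given for it. CPVL lies in the stretch of chromosome 7 and FAM167A in the stretch of chromosome 8 whose genes were mostly lower. SUN3 lies in the second of 4 equal parts of chromosome 7 by gene order, whose median log2 difference was -0.14.

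**Figure D3:**
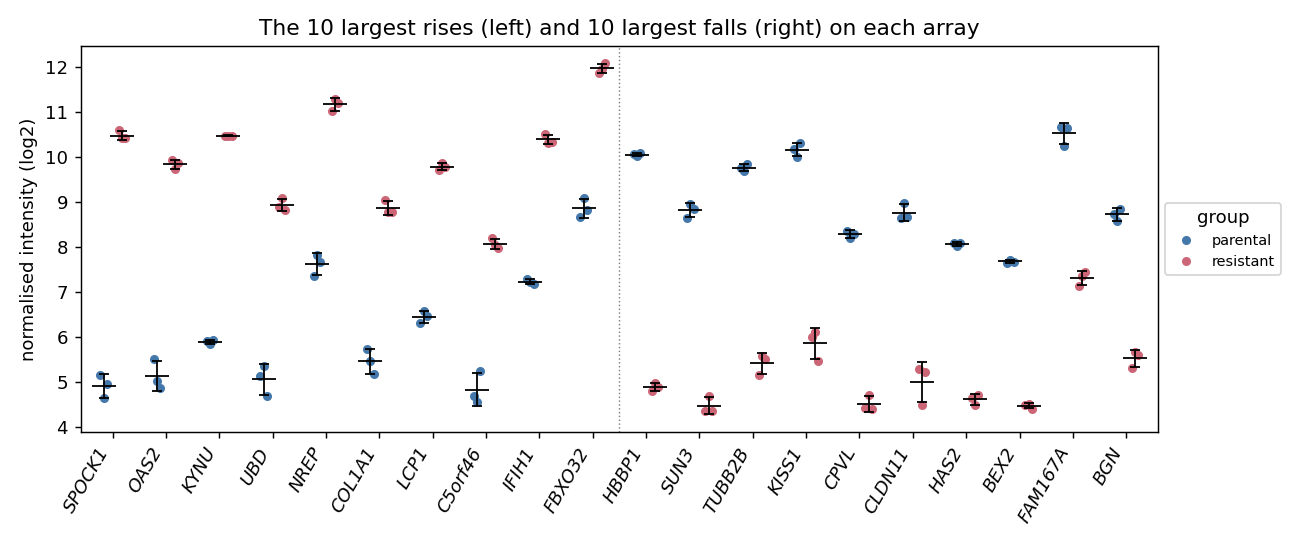
Normalised log2 intensity (vertical axis) of the genes with the 10 largest rises and the 10 largest falls, with 3 parental (blue) and 3 resistant (red) arrays per gene as points and the mean ± SD as bars. The groups do not overlap for any of the 20 genes, from SPOCK1 (log2 difference 5.57) to HBBP1 (at least 34.2-fold lower). HBBP1, SUN3, CPVL, HAS2 and BEX2 were detected on no resistant array by the probe drawn.

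Markers of mesothelial cells, the cells of origin of mesothelioma, moved apart. Of 6 measured markers calretinin (CALB2) rose by 2.74, podoplanin (PDPN), detected on 1 of the 3 resistant arrays, fell by 2.38, LRRN4 fell by 0.79 and BNC1 fell by 0.61, and 1 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.555, and adjusted p = 0.708 with an estimated correlation). The size of the CALB2 rise depended on the probe. Its brightest probe went from a parental mean of 5.85 to a resistant mean of 8.59. A second probe, detected on all arrays, went from 5.67 to 6.27. Epithelial junction and keratin genes went both ways, with 4 of 15 higher and 4 lower, and 4 and 5 when adjusted over the list alone, and 4 and 7 under median scaling (camera adjusted p = 0.996, and adjusted p = 0.995 with an estimated correlation). Keratin 7 (KRT7) rose by 1.92 and the adhesion molecule EPCAM, detected on 1 of the 3 resistant arrays, fell by 2.02. Among receptor tyrosine kinases 5 of 16 rose and 2 fell, also when adjusted over the list alone, against 2 higher and 4 lower under median scaling, with DDR1 higher by 0.87 and EGFR lower by a log2 difference of -0.84 (camera adjusted p = 0.855, and adjusted p = 0.854 with an estimated correlation). Of 10 endothelial markers on the array 1 was detected on all resistant and 2 on all parental arrays, and of 11 lung epithelial markers 1 and 2. TIE1 and SCGB3A1, the called members of these 2 lists, were at least 1.91-fold and 1.22-fold lower.

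Lists of central metabolism did not pass the camera test. Of 21 glycolysis genes 3 rose and 5 fell, with ENO2 and HK1 lower by log2 differences of -1.96 and -1.10, ENO2 with detection on 1 of the 3 resistant arrays, and PKM higher by 0.54 (adjusted p = 0.583, and 0.838 as the adjusted p with an estimated correlation). Of 17 hypoxia targets 5 rose and 5 fell, with NDRG1 and LOX higher by 0.90 and 0.88 and ADM lower by a log2 difference of -1.13 (adjusted p = 0.855, and adjusted p = 0.854 with an estimated correlation). Of 23 genes of the TCA cycle and malate-aspartate shuttle 4 rose and 6 fell, with the cytosolic aspartate transaminase GOT1 lower by a log2 difference of -1.04 and IDH1, whose call was lost with any of 3 arrays left out, higher by 0.59, and of 23 genes of nucleotide synthesis 2 rose and 6 fell, with PRPS1 higher by 0.71 and PRPS2 lower by a log2 difference of -0.42. Of 24 genes of cholesterol and fatty acid synthesis 2 rose and 4 fell, with TM7SF2 lower by a log2 difference of -0.81 and INSIG1 higher by 0.57. Each of these 3 lists had adjusted p = 0.583 and adjusted p = 0.723 with an estimated correlation. Adjusted over the list alone, the counts differed for hypoxia targets (6 lower) and nucleotide synthesis (5 lower). The balance depended on the scaling, and median scaling shifted the median of all genes by -0.15. Under it 2 rose and 9 fell for glycolysis, 5 and 6 for hypoxia targets and 2 and 11 for the TCA cycle. For nucleotide synthesis the counts were 2 and 11, and for cholesterol and fatty acid synthesis 1 and 11.

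Stress and housekeeping lists did not pass either. Of 17 NRF2 targets 3 rose and 4 fell, with the steroid reductase AKR1C3 higher by 1.37 and SRXN1 lower by a log2 difference of -0.99 (adjusted p = 0.855, and adjusted p = 0.854 with an estimated correlation). Of 32 autophagy and lysosome genes 10 rose and 5 fell, with WIPI1 and GABARAPL1 higher by 1.20 and 1.11 and MAP1LC3A, detected on 2 of the 3 resistant arrays, lower by a log2 difference of -2.35 (adjusted p = 0.583, and adjusted p = 0.723 with an estimated correlation). Of 16 genes of the unfolded protein response 6 rose and 2 fell, with PDIA6 higher by 0.72 and EDEM1 lower by a log2 difference of -0.56 (adjusted p = 0.586, and adjusted p = 0.838 with an estimated correlation). Of 15 histone and chromatin modifiers 2 rose and 1 fell, with KDM5B higher by 0.77 and UHRF1, whose call was lost in 6 of 19 other settings, lower by a log2 difference of -0.30 (adjusted p = 0.998, also with an estimated correlation), and of 4 drug efflux pumps 2 rose and 1, ABCC4, fell (adjusted p = 0.826, and adjusted p = 0.854 with an estimated correlation). Of 19 reference genes 3 rose and 4 fell, with YWHAZ higher by 0.38 and PPIA lower by a log2 difference of -1.35 (adjusted p = 0.996, and adjusted p = 0.995 with an estimated correlation), and under median scaling 1 rose and 8 fell. No probe of PPIA was detected at 0.01 on all arrays, so its fall rests on a weakly detected probe. The counts of other lists in this paragraph also moved under median scaling, to 8 higher and 12 lower for autophagy and lysosome genes, 2 higher and 6 lower for the unfolded protein response, 2 higher and 6 lower for chromatin modifiers, 3 higher and 6 lower for NRF2 targets, and 1 each way for drug efflux pumps. Adjusted over the list alone, the counts differed for autophagy and lysosome genes (6 lower) and chromatin modifiers (none lower).

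Across all genes, 4838 of 10672 (45.3%) differed at an adjusted p under 0.05 by limma, 2384 higher and 2454 lower in the resistant cells, with a median absolute log2 difference of 0.51. Of these, 546 also differed by at least 2-fold, 274 higher and 272 lower. Groups did not overlap for 56.0% of the genes, against 10% by chance for 3 against 3. Scaling the arrays to a common median in place of quantile normalisation shifted the median of all genes by -0.15 and gave 1466 higher and 3774 lower genes (28.0% higher, against 49.3%), and without background correction 198 genes passed 2-fold. Of the 137 called genes picked by the rule for named genes, apart from ASS1, 59 had a log2 difference smaller by more than 1.5 times without background correction, and 56 with the deposited log2 values. Of the 29 gene lists tested, 9 passed with the preset correlation and none with an estimated correlation (8 had an unadjusted p under 0.05). For p53 targets, antigen presentation, transporters and mesenchymal genes the estimates were -0.043, -0.0228, -0.0206 and -0.0068, below the preset 0.01. A higher correlation therefore does not account for their lost calls. With fry, which asks whether the genes of a list move one way without comparing them with other genes, 17 passed.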

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

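Probes without a gene name in the annotation used here stood outside the comparison of genes. Of 3646 such probes that passed the detection filter, 383 were higher in the resistant cells than in the parental control cells and 509 were lower, at an adjusted p under 0.05 by limma over these probes. The higher probes were singled out because they lie in data that the gene comparison does not use, above the level in the control samples. More of the unnamed probes were lower than higher, and a smaller share of them was called than of the genes (45.3%). No explanation for these calls was tested.

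The tests of explanations in the rest of this part were chosen after the results had been seen. The comparison of 3 arrays with 3 allows 10 splits, too few for a share under 0.05. The real split (1 of the 10) gave 2384 higher and 2454 lower genes, and the highest count in another split was 0 for either direction by limma, with 111 to 242 genes at an unadjusted p under 0.05. It gave 546 genes past 2-fold (1 of the 10 splits with as many), against a highest count of 0. It also gave 9 gene lists (again 1 of the 10 splits with as many), but the 9 mixed splits gave 3 to 6 lists with the preset correlation, the highest being 6. A mixed split puts 2 arrays of one line with 1 of the other, and so still holds part of the difference between the lines.

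The rise of interferon-stimulated genes was weighed against other cells in the cultures and against the scaling of the arrays. If leukocytes had brought these transcripts, the abundant leukocyte genes should be detected on the resistant arrays, but 1 of 15 markers, CD68, was detected on all 3 resistant arrays, and it was also the 1 detected on all 3 parental arrays. PTPRC, LYZ, TYROBP and CD53 were detected on no array, which argues against leukocytes as the source. Relative to all genes the list median stayed at or above 1.08 over 7 scalings, against an SD of 0.11 over the resistant arrays. The choice among these scalings therefore did not make the rise relative to other genes. The median of all genes was subtracted first, so a shift of whole arrays was not weighed. A difference between the resistant and the parental line, named by the design, remains open and was not tested apart from the comparison itself.

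The fall of amino acid stress genes was weighed against the lower intensity of the resistant arrays. The list median relative to all genes came no closer to 0 than -0.64 over 7 scalings, with an SD of 0.05 over the resistant arrays. Of 10000 random lists matched on mean expression the lowest median was -0.36, against -0.79 for the list. These lists were drawn after quantile normalisation, which evens the brightness of the arrays, so they cannot weigh the lower intensity. The values over 7 scalings argue against the choice among these scalings as the whole cause. The difference between the lines remains open as a hypothesis.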

How the results depend on the processing

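The counts of higher and lower genes, the ASS1 rise and the shifts of the transporter, ATF4 and tRNA synthetase lists kept their direction and call under the other settings, except as follows. Array weights and the intensity trend were not passed to the list tests, so the list calls under them repeat the main test. The size of the transporter shift of -0.47 varied, to -0.0588 without the detection filter, -0.21 without background correction and -0.23 with the deposited values. Under median scaling it was -0.60, but relative to all genes it was -0.45, against -0.46 in the main setting. The count past 2-fold fell to 198 without background correction, 273 with normexp without detection p-values, 316 with an offset of 50, 362 with detection at 0.01 on all arrays and 204 with the deposited log2 values. Median scaling gave 1466 higher and 3774 lower genes, after shifting the median of all genes by -0.15, and turned the shift of the arginine list to -0.0429, ASL to -0.0429 and MYC to -0.117, none past the threshold. The arginine list shift was 0.29 with detection at 0.01 on all arrays and 0.12 with array weights, against 0.05. With each array left out in turn, the arginine list ranged from -0.0615 to 0.22, ASL from -0.12 to 0.29, MYC from -0.0213 to 0.18, and the polyamine list from -0.24 to -0.20. The polyamine list passed the threshold at -0.19 without background correction, -0.20 with normexp, -0.20 with an offset of 50, -0.20 under cyclic loess, -0.20 without the filter, -0.26 with detection at 0.01 on all arrays and -0.19 with the deposited values, and also without parental replicate 2 and without the chromosome segments named below (adjusted p from 0.00795 to 0.0936 over all settings with the preset correlation, and 0.194 with an estimated correlation). The cause of these differences was not tested. With an estimated correlation 0 of the lists passed, and the transporter (-0.47), ATF4 (-0.79) and tRNA synthetase (-0.40) lists lost their call, with unchanged medians. The 16 genes within 1 Mb of ASS1 had a median of 0.24. Over 140 named genes apart from ASS1 and 19 settings, 2548 of 2622 comparisons gave the same call, 60 lost it, 8 gained it and 6 changed sign. Chosen after the data were seen, leaving out chromosome 22 and the first of 4 equal parts by gene order of chromosomes 7 and 8 gave 2196 higher and 2265 lower genes, all among those called before, and 10 lists. The other genes keep their normalised values in that fit, so little change in their calls was possible. Same-numbered arrays of the groups did not deviate together (correlations of -0.07, -0.001 and 0.05), and 1 of 6 arrays correlated best with its own number. With the replicate number as a block, 2257 genes were higher and 2318 lower. A chip barcode as a block was not run, since the column names give none.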

Other observations

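The patterns in this part, and all tests of them, were chosen after the data had been seen. Whole chromosomes and parts of them shifted between the lines. Of 248 measured genes of chromosome 22, 163 were higher and 6 lower in the resistant cells, with a median log2 difference of 0.48, or 1.39-fold. With chromosomes cut into 4 equal parts by gene order, of the 121 genes in the first part of chromosome 7, 90 were lower and 3 higher (median -0.62), and of the 100 genes in the first part of chromosome 8, 73 were lower and 3 higher (median -0.67). GARS1, CPVL, SP4 and ANLN lie in the former, and SLC7A2, FAM167A and GSR in the latter. The second part of chromosome 7 had a median of -0.14. SUN3, PPIA, TBRG4, EGFR and OGDH, which were lower, lie in it. ASL and ABCB1, with log2 differences of 0.05 and 0.41, lie in it too. Parts 3 and 4 went the other way, with medians of 0.32 and 0.33 on chromosome 8 and 0.12 and 0.15 on chromosome 7, and neither chromosome passed as a whole (adjusted p = 0.360 for chromosome 8 and 0.0627 for chromosome 7). TP53INP1, YWHAZ, FBXO32 and NDRG1, which rose, lie in these parts of chromosome 8, as does HAS2, which was lower. Smaller shifts ran along all of chromosome 2 (median 0.24), chromosome 20 (-0.25) and chromosome 3 (-0.23). Of 23 chromosomes tested with camera 8 were past the threshold, namely 2, 3, 5, 6, 10, 19, 20 and 22. With an estimated correlation 7 of these passed, all but chromosome 19. Chromosome 22 had camera adjusted p = 8.28e-17, and adjusted p = 0.0176 with an estimated correlation.

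Gene families defined by the stem of the symbol were tested as well, 178 families of at least 8 genes. Of these 4 passed with the preset correlation, and each had adjusted p = 0.682 with an estimated correlation. By the preset correlation genes of the mitochondrial ribosome were lower, with 24 of 49 MRPL genes lower and 1 higher (median -0.22, adjusted p = 0.00391) and 14 of 29 MRPS genes lower and none higher (median -0.23, adjusted p = 0.0272). Collagen genes were higher, with 11 of 18 higher and 2 lower (median 0.59, adjusted p = 0.0345), and 7 of the 8 IFI genes rose (adjusted p = 0.00361).

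The chromosome 22 shift was weighed against 3 technical readings and a relative gain of the chromosome. Relative to all genes its median stayed at or above 0.29 over 7 scalings (SD 0.03 over the resistant arrays). The GC-rich, gene-dense chromosomes 16, 17 and 19 had medians of 0.07, -0.02 and 0.11. Of them chromosome 19 was itself past the camera threshold (adjusted p = 0.0376, and adjusted p = 0.218 with an estimated correlation). Neither the choice among these scalings nor a shift shared with those chromosomes therefore accounts for the whole of the chromosome 22 shift. All 4 parts of the chromosome had medians of 0.44 or more, above the 0.06 that bounded 95% of random lists matched to the whole chromosome in size and mean expression, which argues against a few strong genes or one segment. With 87.1% of its genes positive, the pattern has the form that more copies of chromosome 22 in the resistant than in the parental cells may give. The difference cannot tell which of the lines changed. A difference in copies stays a hypothesis, since DNA copy number was not analysed here. ATF4, which lies on chromosome 22, was nevertheless lower, with a log2 difference of -0.65.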
